A study of Mus musculus with 10 samples.

How the data were processed

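Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on primary macrophages grown from the bone marrow of C57BL/6J mice, and 10 libraries were analysed here. RelA (the p65 subunit of the transcription factor NF-κB) was precipitated in 7 libraries and the glucocorticoid receptor (GR) in 2, and 1 library held input DNA of untreated cells. Per the labels' protocols, cells for RelA were cross-linked with 1% formaldehyde for 10 min. Cells for GR were first treated with the protein cross-linker disuccinimidyl glutarate at 2 mM for 30 min and then with formaldehyde, a procedure meant to hold receptor that sits on DNA through another protein as well as receptor bound to DNA itself. Chromatin was sheared to 400 to 500 bp, 200 µg entered each precipitation, and single-end reads of 51 nt were sequenced.

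The authors made 1 list of enriched regions per library, and those lists are the only measurements used here. Reads were processed with CASAVA and placed on the mouse genome build mm9, per the submitters' processing notes. The region caller, its version, its threshold and any duplicate filter are not given in the labels or the processing notes. Each deposited list gives positions and 4 values per region. The highest and the mean tag density are signal values, per the file headers; how the authors scaled them, and whether input was subtracted, is not stated. The score is a z-score per region, per the file headers, and the deposited p-value is that of the same region, printed as 0 where it was very small. These are the authors' own values per region. They were used only to describe, rank or filter regions within a list, except where tag densities or scores of several libraries are set side by side and the unknown scaling is named, or where 1 bound was applied to several lists. The lowest score in a list ran from 8.88 to 10.9, so the lists were not cut at 1 common score.

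Each condition had 1 library. No p-value or test between conditions was computed, since the spread between replicates is unknown. Shares of regions carry Wilson 95% intervals, which cover counting error only. Chance placement was described by moving the second list along its chromosomes by random circular shifts, 1000 times, and taking the mean, lowest and highest share. The depth of the libraries is not given in the sources used here. It was inferred in relative terms: tag densities were read as scaled tag counts less scaled input counts, and the scale of the tag counts, a step proper to each list, was searched for among its low values; relative depth is then the inverse of the step. Whole multiples of the step alone (within 0.0006) made up 93.9% of the values tested for GR with dexamethasone and 78.0% for GR with both agents, but only 6.88 to 24.6% in the RelA lists. With up to 6 of a second, fitted step taken off, the share was 86.7 to 94.5% in the RelA lists at 3 h, at 8 h and with late treatment, 66.7% at 0 h, 68.4% with pretreatment alone, and 51.5% and 33.3% with pretreatment and 3 h or 8 h of lipopolysaccharide, so the steps of the short lists are the less certain. The second step was 0.661 to 0.707 in the RelA lists, 0.039 for GR with dexamethasone and 0.597 for GR with both agents. It differed between lists and from the step of the input list, so whether it stands for input counts is not known. In 9 of the 10 lists more values lay on 1 step (within 0.0003) than in any of 20 lists with values moved at random, and the RelA list after dexamethasone pretreatment and 8 h of lipopolysaccharide was the exception, with 3 values on the step against 3. The step was 0.979 for RelA at 0 h, 0.815 at 3 h, 0.970 at 8 h, 1.06 with pretreatment alone, 1.01 with pretreatment and 3 h, and 1.21 with late treatment. It was 0.312 for input, 0.598 for GR with dexamethasone and 0.668 for GR with both agents. These values are an inference from the files and not a count of reads.

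Before the data were examined, the following choices were made: regions overlapped when they shared at least 1 bp; ChIP regions overlapping an input region were left out of every overlap; shares were also given by quintile of the authors' score; and in each class of regions (in both lists or in 1 list alone) the 5 with the highest score were those named. Alternatives chosen at the same time were an overlap of at least 50% of both regions, centres within 250 bp, the higher-scoring part (50%) of each list, input-overlapping regions kept, the 10000 highest-scoring GR regions, merging of regions within 500 bp, and coverage of at least 50% by input regions. After the data had been seen, a highest tag density of at least 10 (high density) or below 5 (low density), a density of at least 15 steps, a score of at least 11 in every list, quintiles of tag density, groups of RelA regions within 10000 bp (12500 bp at first), and the comparison of GR between classes of RelA regions were added.

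The gene tables at hand were on another build (GRCm38.p6) than the files, and no genome sequence of mm9 was used. The analyses of 15 gene lists, of positions relative to genes and of 7 sequence motifs that had been planned were therefore not run, and regions are named by their mm9 position as deposited, with no gene. The overlap code was tested on 2000 simulated regions made from the GR list with dexamethasone, where it found 300 of 300 true overlaps at 1 bp and 0 false ones, and the step search recovered 3 of 3 simulated steps. Grouping of RelA regions by chance was described by placing each list's regions at random on their chromosomes 100 times, and by cutting the longer lists at random to the length of the shorter 100 times. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.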

Results

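Macrophages were treated with lipopolysaccharide (LPS), the bacterial cell wall component that activates NF-κB through Toll-like receptor 4, with the synthetic glucocorticoid dexamethasone (Dex), or with both. RelA was profiled after 0, 3 and 8 h of LPS without Dex, after the same times with Dex given 3 h before LPS, and after 8 h of LPS with Dex given late. The labels do not give the hour of the late Dex. Conditions and times are those of the sample labels. The names under which some lists were deposited, among them those at 0 h and with late Dex, carry further times that the labels do not explain. GR was profiled with Dex and with LPS and Dex, with no times in the labels. The series title names the timing of glucocorticoid treatment as its subject. The 10 lists held 115077 regions in all, with 1 library per condition, and every position below is on mm9 as deposited.

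The number of regions separated the conditions by orders of magnitude. For RelA, 83 regions were listed at 0 h, 5017 at 3 h of LPS and 1890 at 8 h. After Dex pretreatment the lists held 75 regions at 0 h, 84 at 3 h and 78 at 8 h of LPS, and late Dex left 250 at 8 h. GR lists were longer, with 55196 regions for Dex and 51639 for LPS and Dex. Covered length ran from 36165 bp with pretreatment alone to 2848638 bp for RelA at 3 h and 22624470 bp for GR with LPS and Dex, while mean widths stayed between 404 and 568 bp in the ChIP lists. The input list held 765 regions over 508662 bp with a mean width of 665 bp, and 235 of them lay on chromosome X.

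Part of the short RelA lists was shared with input DNA. Input regions met 43.4% of the RelA regions at 0 h (Wilson 95% interval 33.2 to 54.1), 42.7% with pretreatment alone (32.1 to 53.9), 60.7% with pretreatment and 3 h of LPS (50.0 to 70.5) and 80.8% with pretreatment and 8 h (70.7 to 88.0). The share was 10.0% for late Dex (6.87 to 14.3), and 0.897%, 0.635%, 0.582% and 0.544% for RelA at 3 h, RelA at 8 h, GR with Dex and GR with LPS and Dex. Outside input regions, RelA had 47 regions at 0 h, 4972 at 3 h, 1878 at 8 h, 43, 33 and 15 after pretreatment at 0, 3 and 8 h, and 225 with late Dex. GR had 54875 with Dex and 51358 with LPS and Dex.

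**Figure D1:**
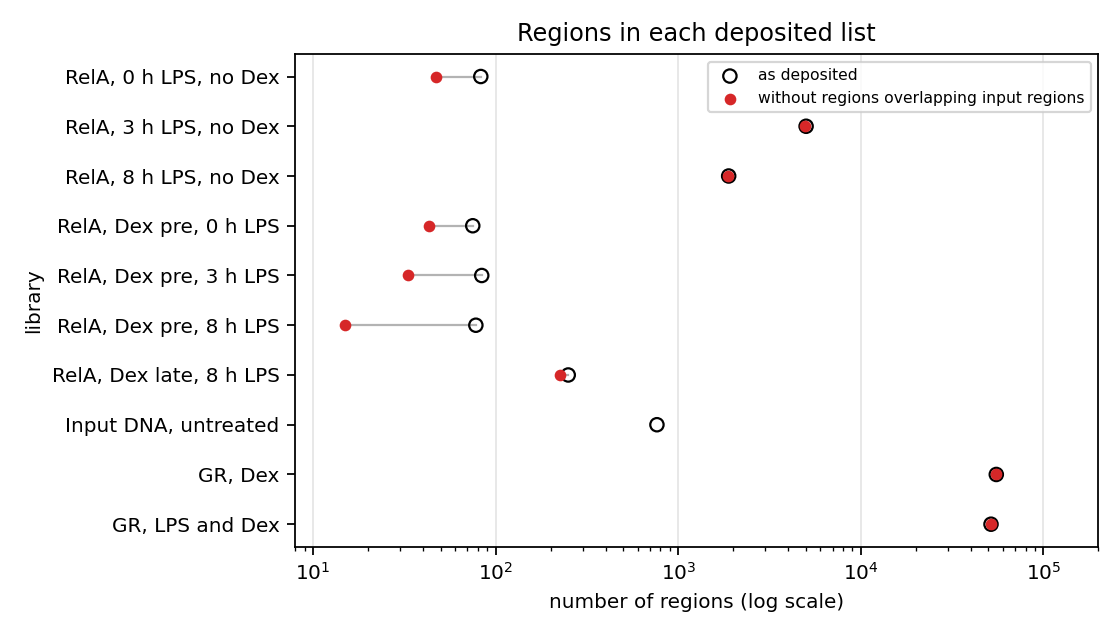
Number of regions in each of the 10 lists on a log axis, as deposited (open circles) and without regions that overlap an input region (red points; not defined for the input list). The 3 lists of Dex-pretreated RelA libraries fall from 75, 84 and 78 regions to 43, 33 and 15, while the RelA lists at 3 h and 8 h of LPS without Dex hardly move.

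The time course asked where RelA sat before LPS, early and late. Few RelA regions were called in resting cells, many at 3 h and fewer at 8 h, most of which were also called at 3 h. Of the 1878 regions at 8 h, 83.9% (82.2 to 85.5) were also called at 3 h, and of the 4972 at 3 h, 31.3% (30.0 to 32.6) were called at 8 h. Shifted lists gave means of 0.223% and 0.0838%. Of the 47 resting regions, 78.7% (65.1 to 88.0) were called again at 3 h and 76.6% (62.8 to 86.4) at 8 h. The share at 3 h was 40.4% when at least 50% of both regions had to be shared. With input-overlapping regions kept it was 63.9%.

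Regions called at both LPS times were the stronger ones at 3 h. Their median highest tag density there was 27.5 (quartiles 20.0 and 38.9; 1556 regions) with a median width of 703 bp, against 16.7 (13.5 and 20.8) and 464 bp for the 3416 regions called at 3 h alone. The share called again at 8 h rose with the authors' score at 3 h, from 6.93% (5.52 to 8.68) in the lowest quintile to 77.1% (74.4 to 79.6) in the highest. A further 302 regions were called at 8 h alone, with a median tag density of 20.3. The lists began at different scores, 8.88 at 3 h and 10.9 at 8 h, and the gap in length between them depended on this: with 11 as the lowest score, and regions overlapping input kept, 3353 regions remained at 3 h and 1863 at 8 h, so the difference fell from 3127 to 1490. Outside input, 42.1% of the 3 h regions of that score were then called at 8 h and 76.7% of the 8 h regions at 3 h.

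The highest scores among regions of both times were at chromosome 10, 77597384 to 77599198 (score 122), chromosome 17, 13202574 to 13203628 (111), chromosome 2, 167602606 to 167603704 (110), chromosome 10, 18734572 to 18735829 (109.9) and chromosome 19, 22022084 to 22023086 (104). All but the last were also called without LPS. The strongest regions of 3 h alone were at chromosome 12, 120345864 to 120346821 (53.5) and 8393101 to 8394178 (52.5), chromosome 13, 42469351 to 42470251 (50.6), chromosome 1, 80599448 to 80600287 (50.4) and chromosome 3, 148882750 to 148883835 (47.9). The regions of chromosomes 13 and 1 were called in the 8 h library with late Dex, although not at 8 h without Dex. Regions of 8 h alone were led by chromosome 3, 60275768 to 60276480 (37.3), chromosome 17, 10932866 to 10933565 (28.4), chromosome 16, 30678829 to 30679531 (27.2), chromosome 10, 96904981 to 96905702 (26.6) and chromosome 13, 75358971 to 75359862 (25.7). All 5 met a GR region of the LPS and Dex list and none met one of the Dex list.

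**Figure D2:**
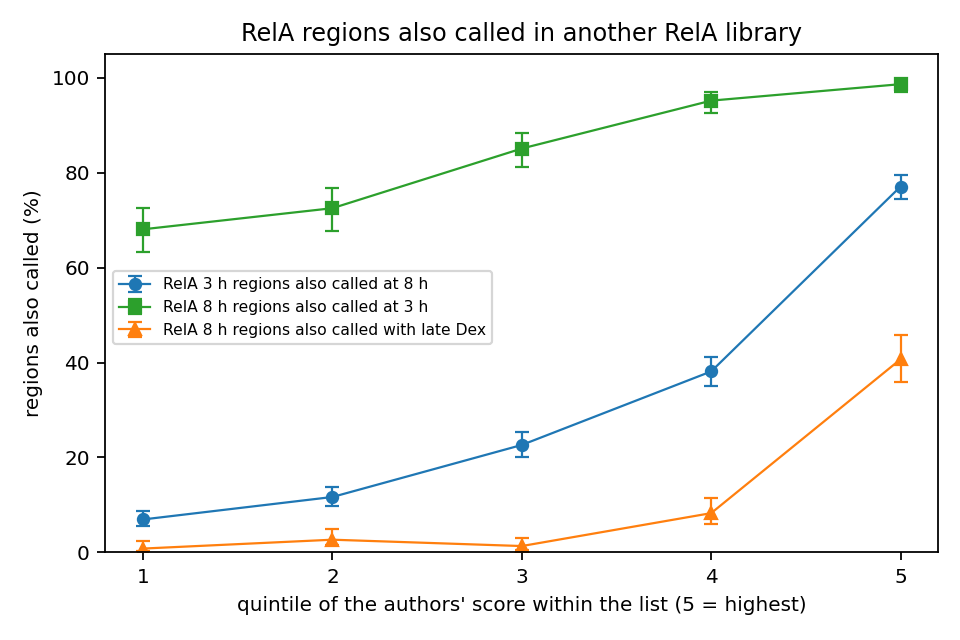
Percent of RelA regions outside input regions that were also called in a second RelA library, by quintile of the authors' score within the first list (bars: Wilson 95% intervals, counting error only). Sharing rises with the score, to 77.1% for 3 h regions called at 8 h, 98.7% for 8 h regions called at 3 h and 40.7% for 8 h regions called with late Dex.

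Dex given before LPS was set against LPS alone at each time. Outside input regions, the pretreated lists held 33 regions at 3 h of LPS against 4972 without Dex, and 15 at 8 h against 1878. Only 12 of the 4972 regions at 3 h, 0.241% (0.138 to 0.421), were found in the pretreated library, and 3 of the 1878 at 8 h, 0.160% (0.0543 to 0.469). Without LPS, Dex made little difference to the length of the list, 43 regions against 47, and 19 of the 47, 40.4% (27.6 to 54.7), were shared. The lists are short, and no replicate shows how far a repeat of 1 condition would differ.

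The 12 regions left at 3 h were among the strongest of the 3 h list, with a median tag density of 89.8 (67.7 and 126) against 18.5 for the other 4960. Their 5 highest scores were at chromosome 10, 77597384 to 77599198 and 18734572 to 18735829, chromosome 2, 167602606 to 167603704, chromosome 19, 6945023 to 6946053 (98.7) and chromosome 3, 131360829 to 131361842 (82.3). At the region of chromosome 10 from 18734572, the authors' score, whose comparability between libraries is not known, was 17.8 at 0 h, 109.9 at 3 h and 91.4 at 8 h without Dex. It was 12.6, 18.7 and not called in the pretreated libraries at the same times, and 28.8 with late Dex. The other named regions did not share that rise from 0 h to 3 h with pretreatment. The score went from 18.5 to 11.7 at the region of chromosome 2 and from 12.8 to 10.3 at chromosome 10 from 77597384. At chromosome 3 it went from 13.1 to 13.7, and the region of chromosome 19 was not called with pretreatment alone. Most strong regions were not called in the pretreated 3 h library, since the 3 h list without Dex held 251 regions with a tag density of 50 or more. Examples of like strength were chromosome 17, 13202574 to 13203628 and chromosome 19, 22022084 to 22023086. The 21 regions called with pretreatment but not without it at 3 h were weak and narrow, with a median tag density of 6.42 and a median width of 251 bp, the smallest width in the list. The highest score among them was 24.0, at chromosome X, 122525862 to 122526237, a region also called at 0 h.

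At 8 h, the 3 regions shared with the pretreated library were at chromosome 19, 6945026 to 6945968 (score 88.7), chromosome 10, 5744225 to 5745130 (24.9) and chromosome 12, 5623193 to 5623468 (12.7). The first overlapped the region of the same chromosome kept at 3 h. The 12 regions of the pretreated 8 h list alone had a median tag density of 6.34 and a median width of 251 bp, and their highest score was 15.8, at chromosome 12, 23466285 to 23466536.

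Late Dex was compared with no Dex and with pretreatment at 8 h of LPS. RelA was called at more regions when Dex came late, 225 against 15 with pretreatment, but at far fewer than the 1878 without Dex. Whether depth or recovery shortened the pretreated 8 h list is open, as set out below. As far as they reflect depth, the tag density steps put the late Dex library at 0.804 of the depth of the 8 h library without Dex. No test of recovery was set for the late Dex library. It held 53.2% (39.2 to 66.7) of the 47 resting RelA regions. The share was 40.4% (27.6 to 54.7) with Dex alone and 76.6% (62.8 to 86.4) at 8 h without Dex. Late Dex was thus not below Dex alone. Both intervals overlap that of late Dex, and LPS differs from the first library, so the share does not settle recovery. The late list was almost wholly contained in the LPS lists: 89.8% of its regions (85.1 to 93.1) were called at 8 h without Dex and 94.2% (90.4 to 96.6) at 3 h. Conversely 10.8% of the 8 h regions (9.43 to 12.2) were called with late Dex, against the 0.160% with pretreatment.

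The regions called with late Dex were the stronger ones of the 8 h list. Their median tag density without Dex was 53.4 (37.4 and 71.6; 202 regions), against 24.2 (19.7 and 31.2) for the 1676 others, and the share called rose from 0.798% (0.272 to 2.32) in the lowest score quintile to 40.7% (35.8 to 45.7) in the highest. Highest scores among them were at chromosome 15, 6518818 to 6519807 (108), chromosome 10, 37057705 to 37058881 (99.8), chromosome 17, 18037481 to 18038376 (94.5) and 13202580 to 13203586 (93.5), and chromosome 10, 18734654 to 18735834 (91.4). Strong regions without a late Dex counterpart lay at chromosome 11, 64468352 to 64469331 (64.6), chromosome 2, 136762371 to 136763206 (61.7), chromosome 11, 43198425 to 43199378 (54.9), chromosome 15, 67612236 to 67613083 (54.8) and chromosome 16, 24766312 to 24767237 (46.9). All 5 met a GR region of the LPS and Dex list, and the first 4 also one of the Dex list. Only 23 regions were called with late Dex and not without Dex, led by chromosome 13, 42469443 to 42470078 (20.1) and chromosome 18, 62326399 to 62326964 (14.8), both of which were called at 3 h.

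The GR libraries asked whether LPS alters where GR sits when Dex is present. As deposited the lists were of like length, yet only 35.0% of the Dex regions (34.6 to 35.4) met a region of LPS and Dex, and 37.4% (36.9 to 37.8) conversely, against means of 1.60% and 1.69% for shifted lists. Most regions had a low tag density: 48369 regions with Dex and 32258 with LPS and Dex lay below 5, 2773 and 2734 between 5 and 10, and 3733 and 16366 at 10 and above. The bounds of 5 and 10 were set after this distribution had been seen.

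At high tag density, GR with Dex was nested in GR with LPS and Dex. Of the 3733 regions with Dex, 85.2% (84.1 to 86.3) met 1 of the 16366 with both agents, and 19.4% (18.8 to 20.0) of the latter met 1 of the former, against shifted means of 0.697% and 0.160%. At the 3177 shared regions the highest tag density was higher with LPS and Dex at 85.2%, and the median log2 ratio was 1.16 (quartiles 0.42 and 1.68) on the deposited scale, whose normalization between the libraries is not known. The order of the lists by number therefore depends on tag density. With regions overlapping input kept, 16612 regions with LPS and Dex and 4018 with Dex had a density of at least 10. The number with LPS and Dex minus that with Dex was then 12594, against -3557 as deposited.

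**Figure D3:**
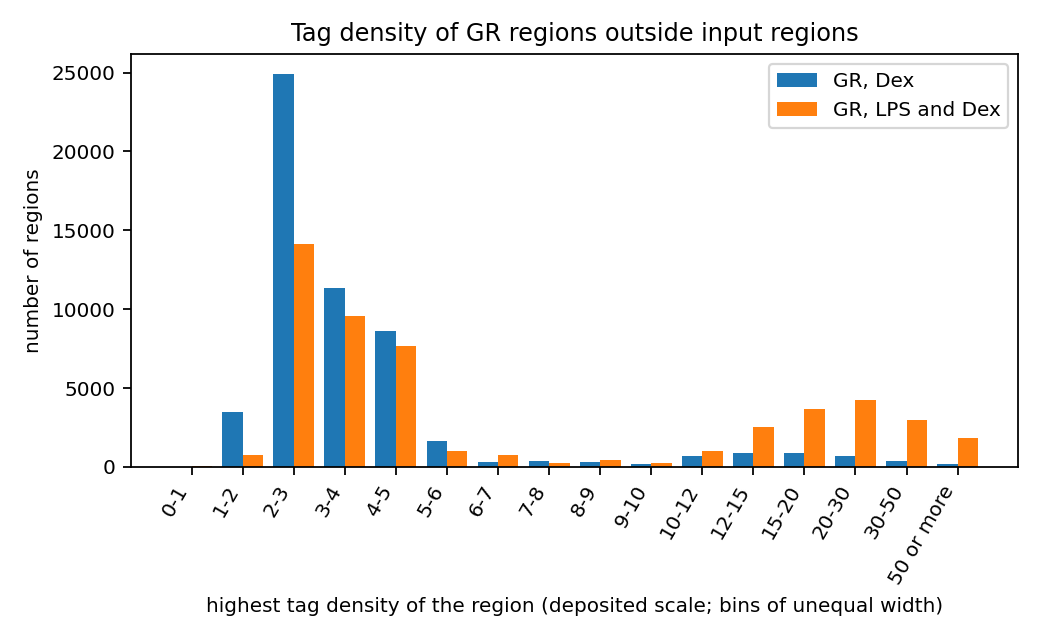
Number of GR regions outside input regions by highest tag density (deposited scale; bins of unequal width) with Dex and with LPS and Dex. Most regions of both lists lie below 5, and 3733 regions with Dex and 16366 with LPS and Dex lie at 10 and above.

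The highest-scoring GR regions of both lists were at chromosome 18, 90771301 to 90772116 (score 1299 with LPS and Dex), chromosome 5, 23641784 to 23643071 (657), chromosome 13, 74665761 to 74668220 (541), chromosome 17, 13245016 to 13245877 (515) and chromosome 7, 107108677 to 107109690 (487). None of these met a RelA region. Their tag densities were 157, 73.5, 97.5, 76.2 and 247, so score and density ranked regions differently. Whether regions of such high scores are GR sites was not tested. By tag density, a value looked at after the scores, the first was chromosome 17, 26671834 to 26673046 (746, with a score of 427). It was also a RelA region at 3 h, at 8 h and with late Dex. Regions of LPS and Dex alone were led by chromosome 9, 119174714 to 119175569 (171), chromosome 11, 72242459 to 72243405 (150.0) and 86409450 to 86410406 (141), chromosome 6, 97874044 to 97874839 (136) and chromosome 16, 76086080 to 76086918 (132). Those of chromosomes 11 and 6 were RelA regions at 3 h. The highest 5 scores among regions of Dex alone ran from 69.4 at chromosome X, 122644952 to 122645331 to 48.8 at chromosome 6, 96920556 to 96921087. The tag densities there were 11.4 and 4.78. These scores are those of the Dex list, and whether they compare with scores of the other GR list is not known. The others of the highest 5 were at chromosome 1, 43835284 to 43835820 (63.2) and 43834467 to 43834997 (59.7), and chromosome 4, 146547237 to 146547694 (54.8).

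RelA regions of LPS without Dex were set against the GR regions of both GR libraries, so the lists compared come from cells treated differently. GR regions of LPS and Dex met 62.0% of the RelA regions at 3 h (60.7 to 63.4) and 85.8% at 8 h (84.2 to 87.3). GR regions of Dex without LPS met 17.5% (16.5 to 18.6) and 18.4% (16.7 to 20.2). Shifted GR lists gave means of 1.82 to 1.85%, so the shares were 33.5 and 46.5 times chance placement with both agents and 9.58 and 10.1 times with Dex. Among the 225 RelA regions with late Dex, 95.1% (91.5 to 97.2) met GR of LPS and Dex and 31.6% (25.8 to 37.9) GR of Dex. In the highest quintile of the 8 h score, high-density GR of LPS and Dex met 97.4% of the 153 regions called with late Dex. It met 98.2% of the 223 others there, so no excess was seen. In the next quintile it met 96.8% of 31 and 90.7% of 344. Each lower quintile held at most 10 regions called with late Dex, all with such GR, against 74.8 to 82.2% of the others. Of the 47 resting RelA regions, 39 met GR of LPS and Dex, a share with an interval of 69.9 to 91.1%, and 22 met GR of Dex, 46.8% (33.3 to 60.8). With GR regions of high density alone the shares were 61.0% and 16.3% at 3 h and 85.0% and 17.3% at 8 h. The contrast over chance was then gone, as the high-density list of Dex is the shorter: the shares were 82.96 times chance placement with both agents and 106 times with Dex at 3 h, and 116 and 109 times at 8 h.

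Where RelA and high-density GR of LPS and Dex overlapped, the median distance of their centres was 52.5 bp at 3 h (3035 RelA regions) and 44.0 bp at 8 h (1596). For high-density GR of Dex it was 56.0 bp (810) and 52.0 bp (325). Only overlapping regions were measured, which builds in part of this closeness, and no reference distance was computed. Overlap with all GR regions of LPS and Dex, of high density or not, rose with RelA score at 3 h, from 42.5% (39.5 to 45.6) in the lowest quintile to 85.2% (82.9 to 87.3) in the highest. Seen from GR, RelA at 3 h was found at 25.6% (24.1 to 27.1) of the 3177 high-density regions shared by the GR libraries, at 17.0% (16.4 to 17.7) of the 13189 of LPS and Dex alone, and at 0.726% (0.283 to 1.85) of the 551 of Dex alone. Alone here means without a high-density region in the other list. Only 12807 with both agents and 394 with Dex met no region of the other list at any density. The 551 had a median tag density of 13.1, and 24.0% of them lay on chromosome X, against 2.68% of the 13189 and 7.71% of the 3177. The shared regions were denser than those of LPS and Dex alone (medians of 39.6 and 19.7), and within quintiles of tag density the order turned: high-density regions of LPS and Dex with RelA were found with Dex less often than those without RelA in all 5, from 3.57% against 9.44% in the lowest to 49.6% against 53.1% in the highest. High-density GR regions of LPS and Dex with RelA were also denser in GR tags, with a median of 33.1 (3055 regions) against 20.0 (13311).

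**Figure D4:**
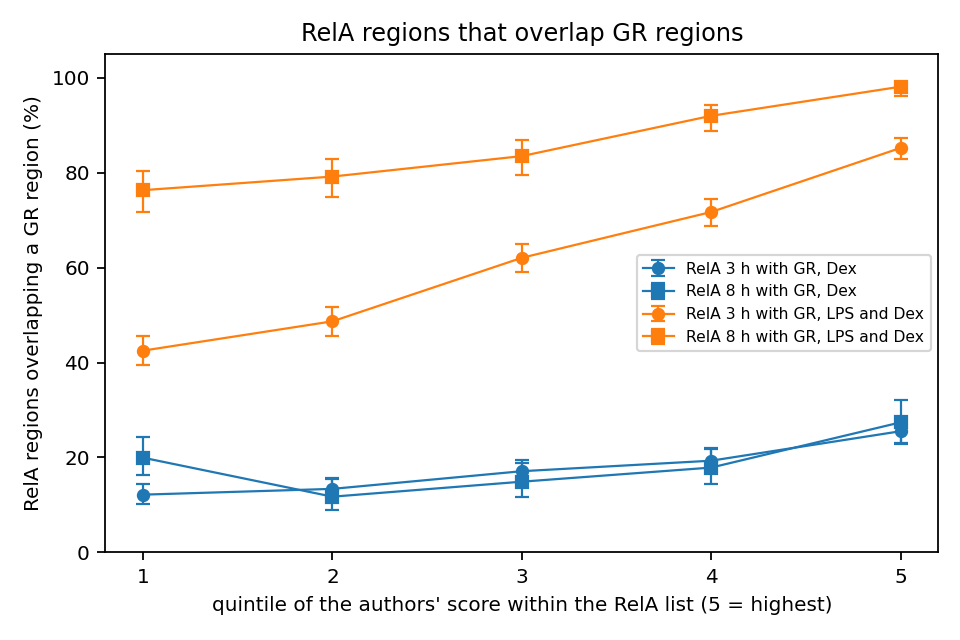
Percent of RelA regions at 3 h and 8 h of LPS that overlap a GR region of either GR library, by quintile of the authors' score within the RelA list (bars: Wilson 95% intervals, counting error only). The shares with LPS and Dex lie between 42.5% and 98.1%, and those with Dex between 11.7% and 27.4%.

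RelA regions that lasted from 3 h to 8 h met GR of LPS and Dex more often than those of 3 h alone, and did so in all 5 quintiles of the 3 h score. High-density GR was found at 88.1% (86.4 to 89.6) of the 1556 lasting regions and at 48.7% (47.0 to 50.4) of the 3416 others. Within quintiles of the 3 h score the lasting regions lay between 82.6% and 90.1% and the others between 38.9% and 66.7%, with a mean difference of 33.8 percentage points (23.4 to 43.7 over quintiles). For GR with Dex the mean difference was 0.128 points, from -6.14 to 4.29. Strong RelA regions at 3 h without high-density GR of LPS and Dex existed too, led by chromosome 8, 87499936 to 87500980 (55.2), chromosome 12, 120345864 to 120346821 (53.5), chromosome 3, 148882750 to 148883835 (47.9), chromosome 6, 65539846 to 65540920 (47.3) and chromosome 10, 122331426 to 122332452 (46.9). The GR times are not in the labels, so whether they match the RelA times is not known.

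**Figure D5:**
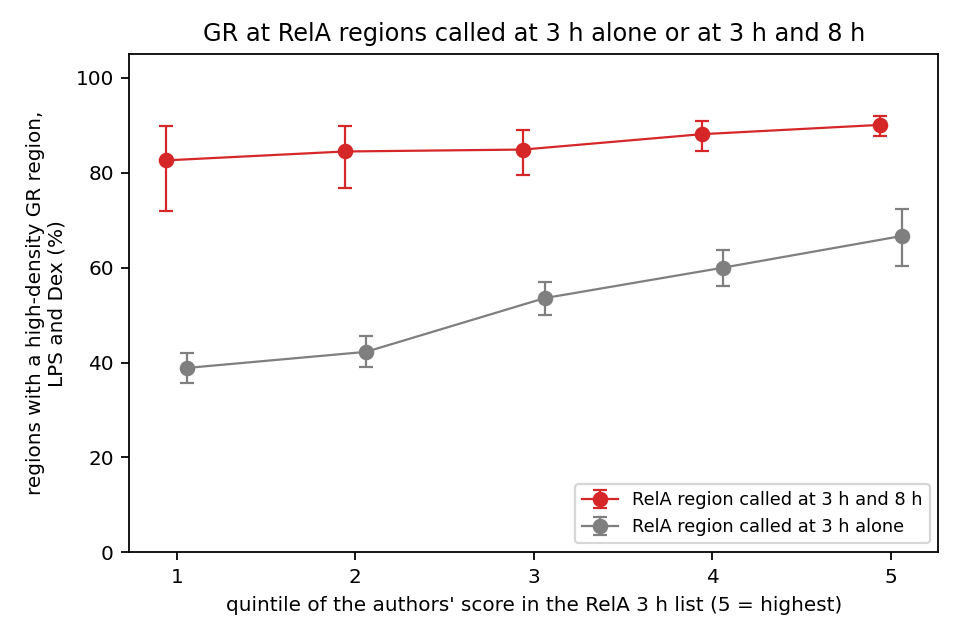
Percent of RelA 3 h regions that overlap a high-density GR region of LPS and Dex (highest tag density of at least 10), for regions called at 3 h and 8 h and for regions called at 3 h alone, by quintile of the authors' score at 3 h (bars: Wilson 95% intervals, counting error only). The lasting regions lie higher in all 5 quintiles.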

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

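The tests in this part were chosen after the region counts had been seen. Outside input regions, LPS moved the number of RelA regions in opposite directions with and without Dex pretreatment. From 0 h to 3 h the number changed by 4925 without Dex and by -10 with pretreatment, and from 0 h to 8 h by 1831 and by -28. These counts stand out because, with input-overlapping regions left out, the direction differed between the arms. It also differed with a tag density of at least 10 outside input, where the pretreated lists held 31, 17 and 2 regions at 0, 3 and 8 h, and at a score of at least 11 with input-overlapping regions kept, where they held 66, 52 and 46, against 64, 3353 and 1863 without Dex. It did not differ as deposited, with 75, 84 and 78 regions in the pretreated lists and 83, 5017 and 1890 without Dex, and with input-overlapping regions kept at a density of at least 10 the pretreated lists held 58, 58 and 63. The direction thus depends on the filter. The difference itself was not tested, since each condition had 1 library.

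The small number of RelA regions after Dex pretreatment and LPS was weighed against lower depth, lower recovery of RelA-bound DNA, and Dex itself. Lower depth was argued against at 3 h, as far as the tag density steps reflect depth: they put the pretreated library at 0.804 of the depth of the 3 h library without Dex, which gave 4972 regions to its 33, and at 0.956 of that of the 8 h library without Dex, which gave 1878. At 8 h the ratio came to 0.917, but that step rested on 3 values, no more than random lists gave, so depth stays open there. Poor recovery would also remove the 47 resting regions, and the pretreated 8 h library held 2.13% of them (0.377 to 11.1), below the 40.4% (27.6 to 54.7) found with Dex alone. A list of 15 regions could hold at most 31.9% of them, so the low share restates the short list, and recovery and treatment cannot be told apart at 8 h. The pretreated 3 h library held 17.0% (8.89 to 30.1), and its 33 regions could hold at most 70.2%. This interval overlaps that of Dex alone, but both treat calls on the same 47 regions as independent. Poor recovery and suppression of RelA binding would both lower this share, so recovery and treatment cannot be told apart at 3 h. Suppression of RelA binding by prior Dex remains a hypothesis that only replicate libraries could test.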

How the results depend on the processing

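Alternatives with a score of at least 11, a tag density of at least 10, a density of at least 15 steps, quintiles of tag density or another gap between grouped regions were chosen after the data had been seen. Over 42 results and 152 alternative values, 90 stayed near the reported value (a count or a difference of counts within 1.5 times, a share within its 95% interval, a mean difference within its range over quintiles), and the cause of the moves below was not tested. The number of GR regions with LPS and Dex minus that with Dex turned from -3557 to 12594 at a density of at least 10 and to 12315 at 15 steps, and was near 0 with regions within 500 bp merged (-406) or a score of 11 (-23). At a density of 10, 4018 regions remained with Dex, 16612 with LPS and Dex and 358 of input, and at 15 steps 4182 with Dex and 16497 with both. Leaving out input regions gave 47 RelA regions at 0 h and 43, 33 and 15 after pretreatment; a score of 11 gave 52 and 46 with pretreatment at 3 h and 8 h. With 50% of both regions shared, the share of 3 h regions called at 8 h was 27.8%, of 3 h and 8 h regions called after pretreatment 0.0603% and 0.0532%, of 8 h regions with late Dex 8.09%, of GR with Dex in LPS and Dex 23.3% and conversely 24.9%, and of RelA at 3 h in the GR lists 13.9% and 50.1%. With centres within 250 bp the GR shares were 30.2% and 32.3%, and those of RelA in GR 16.3% and 58.5%. The higher-scoring part of each list gave 32.7% for 3 h in 8 h, 0.0% for 8 h after pretreatment, 27.9% and 29.8% between GR lists, and 13.1% and 65.6% for RelA in GR. A score of 11 gave 42.1% for 3 h in 8 h, 0.0540% for 8 h after pretreatment and 8.59% for late Dex. Input regions kept gave 0.598% and 0.582% after pretreatment at 3 h and 8 h. The 10000 highest-scoring GR regions shared 19.0% and 19.2%; at high density in both lists the shares were 85.2% and 19.4%, in the list counted 89.4% and 21.7%, and RelA at 3 h met GR of Dex at 16.3%. The lasting RelA regions exceeded those of 3 h alone in GR of LPS and Dex by 29.3 to 34.4 points over 4 alternatives. The alternatives for gene lists, positions relative to genes and motifs were not run, and no replicate could be left out. No paired analysis was possible because each condition had 1 library.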

Other observations

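Of the tests in this part, those on low-density GR regions and on GR depth were chosen after the result was seen, as were the groups of regions described first and their chance values. The test on even recovery of GR, with its bound of 5 points, was set before its result was known. The comparison of its intervals was not part of that rule. RelA regions lay in groups along the genome. At 3 h, 34.6% of the regions lay within 10000 bp of another, in 685 groups, of which 33 held 5 or more, and the share was 27.2% at 8 h and 11.1% with late Dex. A wider gap, used first, gave 37.3%, 29.2% and 12.4%. Regions placed at random on their chromosomes gave means of 4.10%, 1.56% and 0.178%, with highest values of 4.99%, 2.82% and 0.889%. The shares of the lists cannot be compared as they stand, since a longer list has more neighbours: cut at random to the length of the 8 h list, the 3 h list gave a mean of 17.0%, below the 27.2% at 8 h, and cut to the length of the late Dex list, the 3 h and 8 h lists gave 2.44% and 3.87%, below its 11.1%. A random cut is not a matched reference, since the regions called again later were the stronger ones, and no cut by score was made. A single region at 3 h could also be called as 2 later, as at chromosome 13, 20878719 to 20880223 with late Dex. Whether later regions lie in groups more often is thus not known. The largest group spanned chromosome 12, 27125626 to 27154834, with 13 regions at 3 h, 1 at 8 h and 0 with late Dex, and met 1 high-density GR region of LPS and Dex. A group of 12 at chromosome 11, 117820995 to 117853564 held 5 regions at 8 h and 1 with late Dex. A group of 9 at chromosome 14, 103432667 to 103459748 held 7 at 8 h and met 7 high-density GR regions of LPS and Dex. With late Dex, the largest was a group of 3 at chromosome 2, 30780776 to 30785469, where 3 regions each were called at 3 h and at 8 h without Dex.

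A set of 15 RelA regions was called at 0 h, with Dex alone, at 3 h, at 8 h and with late Dex. All 15 met high-density GR of LPS and Dex and 8 met that of Dex, 7 were called with pretreatment and 3 h of LPS, and 0 with pretreatment and 8 h. Their median tag density at 3 h was 94.7. Among all 202 RelA regions at 8 h called with late Dex, 97.5% (94.3 to 98.9) met high-density GR of LPS and Dex. The 15 of 15 is thus near that share and not particular to the set. At 8 h, RelA regions called with late Dex met high-density GR of Dex at 31.7% (25.7 to 38.4; 202 regions), against 15.6% (13.9 to 17.4; 1676) for the others. In the highest score quintile the shares were 30.1% (23.4 to 37.7) and 23.8% (18.7 to 29.8), whose intervals overlap, and in the next 35.5% (21.1 to 53.1; 31 regions) and 15.1% (11.7 to 19.3). The lowest 3 quintiles held 3, 10 and 5 regions called with late Dex, too few to read.

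The larger part of both GR lists had a tag density below 5, and background that the input list does not hold was weighed as its source. These regions had scores near those of the denser ones (medians of 14.7 and 18.7 with LPS and Dex). In the LPS and Dex list 0.0279% of them met a RelA region at 3 h, below the shifted mean of 0.166% and the highest shift of 0.254%, whereas RelA was at 35.0% (33.7 to 36.3) of GR regions with a density of 30 or more. RelA overlap follows GR density, so the split by density builds in a low share, and background placed at random would give the shifted mean and not less. Background and weak GR sites away from RelA cannot be told apart by it. Low-density regions recurred between the GR libraries, at 42.3% (41.7 to 42.8) of those with LPS and Dex against a shifted mean of 1.36%, which a shared background and shared weak GR sites would both give. No input with the GR cross-link was analysed here.

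More high-density GR regions with LPS and Dex than with Dex could come from depth, from recovery, or from LPS. Depth was argued against, as far as the tag density steps reflect it, since they gave the LPS and Dex library 0.894 of the depth of the Dex library. An evenly lower recovery of GR-bound DNA with Dex predicts that, at equal density, regions with and without RelA are found with Dex equally often, within 5 points. The mean difference over density quintiles was -4.51 points, from -5.87 to -3.51, inside the bound set beforehand. That bound decides little, since only 9.44%, 7.25% and 10.6% of the regions without RelA were found with Dex in the lowest 3 quintiles. Regions with RelA were found less often in all 5, with intervals that do not overlap in 4 (1.82 to 6.89% against 8.46 to 10.5% in the lowest). At equal density the shares were thus not equal. High-density regions without RelA also lay on chromosome X more often, 4.06% against 1.90%, so the classes differ in more than RelA. The comparison of intervals was not part of the rule set beforehand, which was met, so evenly lower recovery stays open. These intervals cover counting error and not the spread between libraries, so lower recovery and a gain of GR regions under LPS cannot be told apart without replicates.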
